A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

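RNA abundance was measured by RNA-seq of total RNA from Saccharomyces cerevisiae strain BY4741 in 8 libraries. Per the labels, these form 4 groups of 2 libraries: wild type and rph1 deletion, each untreated and treated with rapamycin. The labels give no dose and no duration. The series also holds 16 chromatin immunoprecipitation (ChIP) and input samples, for FLAG-tagged Rph1 and for RNA polymerase II. Of these, the gene lists that the authors made from the FLAG-Rph1 samples were used, 1 for untreated cells and 1 for rapamycin. The RNA polymerase II ChIP was not analysed here.

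The deposited RNA-seq values are raw read counts per annotated gene, in 7036 entries that are the same in every library. The authors' processing names, per the submitters' processing notes, Trimmomatic 0.38, STAR 2.5.3a, featureCounts 1.6.3 and DESeq2 1.24.0 for the series and the build sacCer3; the role of each tool, the annotation and the use of strand are not stated. Bowtie2 2.3.4.3 and MACS2 2.2.1 are named there too. The deposited FLAG-Rph1 values are, per the file headers, a fold enrichment for each listed gene; the control it is relative to is not stated, nor whether replicates were pooled. Start and end in these lists are those of the gene and not of the peak: this held for all 346 and 579 listed genes, untreated and with rapamycin, that matched the gene table. Neighbouring genes often carry the same value, and the 466 and 705 listed genes hold 373 and 612 distinct values.

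Systematic names were matched to symbols, coordinates and gene types with the gene table of the R64 assembly. Of the 7036 entries, 5956 matched, 173 took a symbol from the FLAG-Rph1 lists, and 907 kept their systematic name. Gene length, the span from start to end with any introns, came from the same table.

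Counts were analysed with edgeR 4.0.16 in R 4.3.3. Entries were kept with filterByExpr at its minimum count of 10, which left 6169 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 8 libraries with a mean per group. It gave 5 comparisons: rapamycin against untreated in each genotype, deletion against wild type in each condition, and the interaction, which is the rapamycin change in the deletion minus that in the wild type. P-values were adjusted by Benjamini-Hochberg within a comparison and called under 0.05. Log2 fold changes are given with their standard error (SE), computed from the F statistic of the same comparison. The SEs of separate comparisons therefore need not combine to that of the interaction. Log2 fold changes are relative to the scaled library, so a change in total RNA per cell would not show. With 2 libraries in a group, all 4 groups shared 1 estimate of the spread. The labels do not state that replicates were separate cultures, so the p-values measure only the spread between these libraries.

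Before the data were examined, 25 gene lists were fixed, from textbook knowledge of yeast and of the rapamycin response: ribosomal protein genes, ribosome biogenesis, RNA polymerase I and III machinery, regulators of ribosomal gene transcription, translation factors with aminoacyl-tRNA synthetases, nitrogen catabolite repression, retrograde response, general stress, autophagy, genes reported as repressed by Rph1, amino acid biosynthesis, sulfur amino acid synthesis, TCA cycle with respiratory chain, glycolysis, mitochondrial ribosomal proteins, proteasome, core histones, cyclins with G1/S genes, iron regulon, phosphate regulon, ergosterol synthesis, a-specific genes, alpha-specific genes, auxotrophic markers, and JmjC demethylases with H3K36 methylation. The groupings, the tests, the rule for named genes and most alternatives were fixed at the same time. Lists were tested with limma 3.58.1 on voom values: camera with a preset correlation of 0.01 between genes, camera again with an estimated correlation, and fry. Camera asks whether a list moved more than other genes. Fry asks whether its members moved, on balance, one way. P-values were adjusted over the lists within a comparison. With an estimated correlation, camera called 0 of 24 lists in every comparison. This included lists in which nearly all members changed one way, so missing this test does not set a list apart. The auxotrophic markers had too few genes past the filter to be tested as a list.

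The rule for named genes took, per comparison, RPH1 and its neighbours; the 8 largest changes in each direction (6 for the interaction and for rapamycin in the deletion) among called genes with a mean of at least 10 CPM (counts scaled by the library's effective total); and up to 4 members of each list, by smallest p-value. For the largest changes, except in the interaction, every library of 1 group had to lie above every library of the other. Members taken from lists and the neighbours of RPH1 had to meet neither this nor the CPM minimum. Where no member of a list was called, its members with the highest mean CPM were taken. Members of lists of 10 or fewer genes were also covered, and for the FLAG-Rph1 lists the 10 highest values, ribosomal protein genes and RPH1. A few genes outside the rule are marked as chosen later.

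The share of ribosomal protein genes in each FLAG-Rph1 list was compared with that of other protein-coding genes by Fisher's exact test, two-sided. The authors' assignment of genes was used, since the lists hold no peak positions. Listed genes were then tested as sets with camera and fry in 4 of the comparisons.

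The edgeR steps were tested on simulated counts with the same groups and depths. Changes were simulated for the deletion with rapamycin alone. There, of 100 genes changed 2-fold, 95% were called, of 100 changed 1.5-fold, 57%, and of 5949 unchanged genes 9 were called. DESeq2 1.42.0 called 94%, 75%, and 21 of 5969 unchanged genes there. In the untreated deletion, where no change was simulated, edgeR called 1 of the 5949 genes and DESeq2 12 of the 5969. The changed genes were drawn from genes above a minimum mean abundance, so recovery was not measured for the rarest transcripts. Counts were drawn independently per gene, so deviations shared by many genes of a library were not simulated. The rates may therefore not carry over to the real libraries.

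Alternatives were DESeq2 in place of edgeR, RLE scaling, TMM scaling without the ribosomal lists, no low-count filter (at least 1 read) and a strict one (at least 10 CPM in 2 libraries), no rRNA, tRNA and mitochondrial entries, a term for the replicate number, only the 4 libraries of a comparison, each of the 8 libraries left out in turn, an estimated correlation, a stricter enrichment, and peak genes without ribosomal protein genes. Ribosomal protein genes with no paralog in the list, and each distinct enrichment value counted once, were chosen after seeing the data.

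The libraries held 18037199 to 24769193 counts. Genes with near-identical copies are uncertain, since how reads shared by copies were counted is not stated; these include most ribosomal protein pairs, histones, HXT6, TEF2, PHO11, PHO12, IMD2, COS12, SNZ1, TDH2, TDH3 and the rRNA genes. The same holds for overlapping and antisense genes and for small nucleolar RNAs (snoRNAs) inside or beside other genes.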

Results

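RNA-seq was collected from wild type and rph1 deletion yeast of strain BY4741, each untreated and treated with rapamycin, a drug that inhibits the growth regulator TORC1. Each of the 4 groups held 2 libraries. Total counts were 18037199 and 24769193 in untreated wild type, 22852808 and 19804182 in untreated deletion, 20630991 and 18937478 in wild type with rapamycin, and 19995299 and 20983031 in deletion with rapamycin. FLAG-Rph1 ChIP from untreated and rapamycin-treated cells was available as 1 list of genes per condition. Log2 fold changes are given ± SE with n = 2 libraries per group, and all p-values of RNA comparisons are edgeR or limma values adjusted for multiple testing. Replicates are not stated to be separate cultures, so these p-values measure only the spread between these libraries. Across genes, which are not independent replicates, Spearman correlations between replicates lay between 0.9849 and 0.9951.

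RPH1 (YER169W; sacCer3, chromosome V, 523369 to 525759) encodes a JmjC histone demethylase and transcriptional repressor. Its reads numbered 1057 and 1850 in untreated wild type, 30 and 43 in untreated deletion, 1695 and 2107 in wild type with rapamycin, and 82 and 45 in deletion with rapamycin. The log2 fold change of the deletion was -5.34 ± 0.34 untreated (adjusted p = 0.000585) and -5.01 ± 0.32 with rapamycin (adjusted p = 0.000584). RPH1 itself did not pass the test for rapamycin in wild type (0.20 ± 0.25, adjusted p = 0.493). Its neighbour ADK2 (YER170W), a mitochondrial adenylate kinase, was higher in the deletion with rapamycin, by 0.78 ± 0.13 (adjusted p = 0.005), and had 0.52 ± 0.14 untreated (adjusted p = 0.0585). Its other neighbour, CCA1, did not pass the test in either condition (-0.17 ± 0.12 and 0.05 ± 0.12). Of the auxotrophic markers, LEU2 had 0 reads in all libraries, URA3 and MET17 had 0 or 1, and HIS3 had 1391 to 8201. HIS3 rose with rapamycin in both genotypes and was lower in the deletion with rapamycin, by -1.03 ± 0.08 (adjusted p = 0.000613).

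Rapamycin in wild type cells lowered transcripts of the machinery that makes ribosomes and raised those for the use of poor nitrogen sources. Of 137 ribosomal protein genes, 136 fell, with a median log2 fold change of -3.04, and their share of all counts went from 20.7% and 21.9% to 3.48% and 2.73%. RPL9A (YGL147C; chromosome VII, 227754 to 228329) fell 35.4-fold, by -5.15 ± 0.21 (adjusted p = 1.3e-06), and ASC1, a protein of the small ribosomal subunit, fell 25.5-fold. The GABA permease gene UGA4 (YDL210W; chromosome IV, 84270 to 85985) rose 136-fold, by 7.09 ± 0.14 (adjusted p = 1.89e-07). DAL80, a GATA factor of nitrogen catabolism, rose 107-fold, by 6.75 ± 0.25 (adjusted p = 9.2e-07). CIT2, the peroxisomal citrate synthase of the retrograde response, rose by 4.77 ± 0.40 (adjusted p = 2.11e-05).

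**Figure D1:**
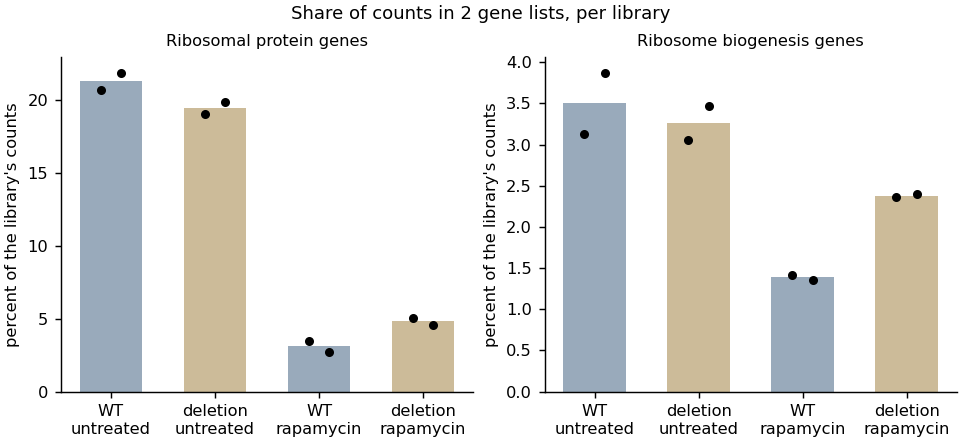
Percent of each library's counts (y axis, from 0) in the 137 ribosomal protein genes and the 149 ribosome biogenesis genes, by group; points are libraries and bars are means of 2. With rapamycin the ribosomal protein share was 3.48% and 2.73% in wild type and 5.07% and 4.56% in the deletion.

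Among the largest increases in wild type were also ALD2, a cytosolic aldehyde dehydrogenase (6.68 ± 0.22), UGA2 of GABA breakdown (6.50 ± 0.22), SNZ1 of vitamin B6 synthesis (6.25 ± 0.20), the carnitine carrier CRC1 (5.84 ± 0.21) and the ammonium permease MEP2 (5.84 ± 0.24). The largest decreases included the snoRNAs SNR49 (-5.27 ± 0.30), SNR44 (-5.12 ± 0.16) and SNR63 (-5.10 ± 0.17), the acid phosphatase PHO3 (-4.13 ± 0.20), and the ribosomal protein genes RPS22A (-4.22 ± 0.15) and RPS9A (-4.07 ± 0.20). The exception among ribosomal protein genes was RPL15B, at 0.26 ± 0.08 (adjusted p = 0.0227). That call was lost without wild type untreated replicate 2 (adjusted p = 0.103), without wild type rapamycin replicate 1 (0.0994), with TMM scaling without the ribosomal lists (0.0567) and with only the 4 wild type libraries (0.0875). All 149 ribosome biogenesis genes fell (median -1.72), among them the helicase ROK1 (-2.26 ± 0.11) and MRT4 (-2.29 ± 0.11). Of 36 genes of the RNA polymerase I and III machinery, 27 fell, such as RPA135 (-2.45 ± 0.13), and 2 rose, TFC3 and BRF1. BRF1 lost its call without wild type untreated replicate 1 (adjusted p = 0.0693) and wild type rapamycin replicate 1 (0.0759). Of 50 translation factor and aminoacyl-tRNA synthetase genes, 48 fell, such as GLN4 (-2.33 ± 0.10). For these 4 lists and for nitrogen catabolite repression and autophagy, camera gave adjusted p from 1.36e-36 to 1.46e-05. With an estimated correlation each of the 6 had adjusted p = 0.497.

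Of 35 genes of nitrogen catabolite repression, 29 rose and 2 fell, with a median of 2.15. The 2 that fell were ATO3, an ammonium exporter (-2.44 ± 0.10), and the asparaginase ASP1 (-1.96 ± 0.10). Of 37 autophagy genes, 29 rose, such as ATG33 (2.80 ± 0.13), and 2 fell, ATG27 and ATG10. All 7 retrograde response genes rose (median 3.39; camera adjusted p = 0.000518; adjusted p = 0.568 with an estimated correlation). Of 50 TCA cycle and respiratory chain genes, 49 rose, such as NDE2 (3.44 ± 0.19) and SDH2 (1.88 ± 0.11); camera gave adjusted p = 2.19e-14, and adjusted p = 0.521 with an estimated correlation. Of 49 general stress genes, 42 rose and none fell, with a median of 1.70, such as the glucan synthase gene GSC2 (3.13 ± 0.10). The list passed camera (adjusted p = 3.6e-08), with adjusted p = 0.629 with an estimated correlation. Of 52 amino acid biosynthesis genes, 35 rose, such as ARG1 (4.74 ± 0.18), and 11 fell, such as LEU9 (-2.65 ± 0.11) and LEU1 (-2.51 ± 0.10); camera gave adjusted p = 0.000325, and adjusted p = 0.621 with an estimated correlation. The list of genes reported as repressed by Rph1 had 5 of 6 higher, ATG8 by 2.07 ± 0.28, and its camera adjusted p = 0.0258 became adjusted p = 0.621 with an estimated correlation. Glycolysis (13 of 18 lower, 2 higher), the proteasome (19 of 33 higher) and core histones (7 of 8 higher) had camera adjusted p = 0.0038, 0.00111 and 0.0311. Each had adjusted p = 0.657 with an estimated correlation. The histone call was lost without wild type untreated replicate 2 (adjusted p = 0.0629) and without wild type rapamycin replicate 1 (0.0753).

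The other lists went both ways or did not pass camera in this comparison. The counts higher and lower were 3 and 4 of 13 regulators of ribosomal gene transcription, 12 and 6 of 25 sulfur amino acid genes, 14 and 9 of 43 mitochondrial ribosomal protein genes, and 3 and 8 of 19 cyclin and G1/S genes. They were 7 and 5 of 23 iron regulon genes, 5 and 2 of 19 phosphate regulon genes, 8 and 8 of 23 ergosterol genes, and 2 and 2 of 6 a-specific genes. Of 6 genes for JmjC demethylases and H3K36 methylation, JHD2 (1.52 ± 0.17) and ECM5 (0.49 ± 0.09) rose and SET2, the H3K36 methyltransferase, fell (-1.68 ± 0.18). In all, 2145 of 6169 genes rose and 2092 fell in wild type, 919 and 898 of them over 2-fold. Rises and falls are relative to the scaled library. The scaling sets the middle of the changes near 0 (median 0.018), so their even split is no result in itself. Adjusted over the list alone, the counts were the same for the ribosomal protein, ribosome biogenesis, autophagy and respiratory lists, and 29 and 3 for nitrogen catabolite repression. By fry, 18 of 24 lists passed.

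In the rph1 deletion, rapamycin also raised most genes of nitrogen catabolite repression and lowered ribosomal protein genes. The ammonium permease MEP2 rose by 6.16 ± 0.24 (adjusted p = 2.58e-06), the general amino acid permease GAP1 by 5.94 ± 0.23 (adjusted p = 2.42e-06) and DAL80 by 7.52 ± 0.25 (adjusted p = 1.24e-06). RPL9A fell by -3.88 ± 0.20 (adjusted p = 6.43e-06), ASC1 by -3.49 ± 0.20 and RPS28B by -3.44 ± 0.27. Again 136 of 137 ribosomal protein genes fell, with a median of -2.29 where the wild type had -3.04. Of 149 ribosome biogenesis genes, 135 fell and 1, RPF1, rose, with a median of -0.76 where the wild type had -1.72.

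RPL15B was again the ribosomal protein gene that rose (0.31 ± 0.08, adjusted p = 0.0142). That call was lost without deletion untreated replicate 2 (adjusted p = 0.108) and deletion rapamycin replicate 1 (0.0767). The call of RPF1 (0.40 ± 0.13, adjusted p = 0.0329) was lost without these libraries (0.138 and 0.184) and without deletion untreated replicate 1 (0.0825). In the deletion 48 of 50 translation genes fell, 21 of 36 polymerase I and III genes fell and 2 rose, and 31 of 35 nitrogen catabolite repression genes rose and 2 fell. All 7 retrograde genes, 35 of 49 stress genes, 25 of 37 autophagy genes and 46 of 50 respiratory genes rose, and 15 of 18 glycolysis genes fell. Camera called these lists, with adjusted p from 4.21e-41 for ribosomal proteins to 0.000583 for glycolysis; each had adjusted p = 0.548 with an estimated correlation. Amino acid biosynthesis had 27 higher and 14 lower (adjusted p = 0.0104, and adjusted p = 0.664 with an estimated correlation). Mitochondrial ribosomal protein genes had 17 higher and 2 lower (adjusted p = 0.019, and adjusted p = 0.548 with an estimated correlation); the call was lost without deletion rapamycin replicate 2 (adjusted p = 0.0792). Of the proteasome genes 4 of 33 fell and none rose, and 3 of 8 histone genes rose; neither list passed camera. Of the genes reported as repressed by Rph1, 5 of 6 rose (camera adjusted p = 0.0158; adjusted p = 0.548 with an estimated correlation).

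In the deletion 1767 genes rose and 1772 fell, 603 and 512 of them over 2-fold. Of the 2145 genes that rose in wild type, 1555 also rose in the deletion, where 614 would be shared if calls were independent. Of the 2092 that fell, 1547 also fell, where 601 would be shared. The changes correlated across genes with r = 0.91, and 17 and 11 genes were called in opposite directions.

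**Figure D2:**
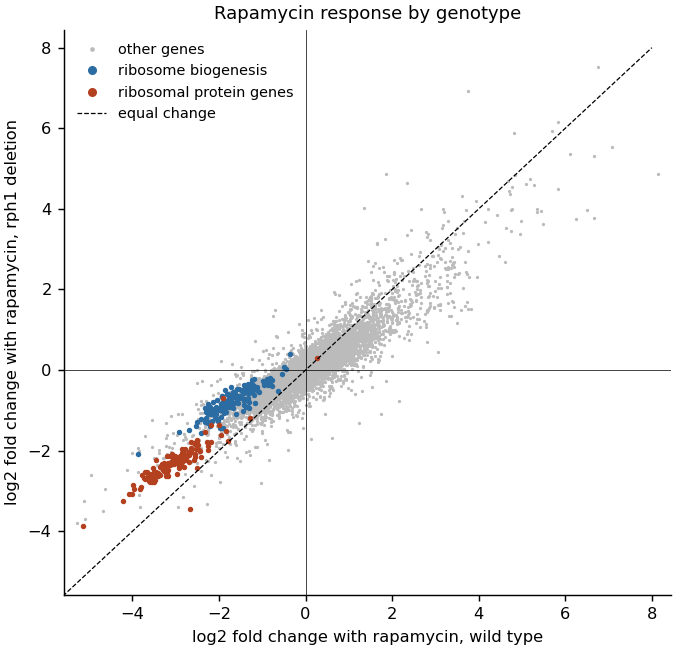
Log2 fold change with rapamycin per gene in wild type (x axis) and in the rph1 deletion (y axis); the dashed line marks equal change. Ribosome biogenesis genes (median -1.72 in wild type, -0.76 in the deletion) and ribosomal protein genes (-3.04 and -2.29) lie mostly above the line.

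In untreated cells the deletion asks what Rph1 does during growth without the drug, and the differences were smaller. YGP1 (YNL160W; chromosome XIV, 336545 to 337609), a secreted cell wall glycoprotein, was 10.5-fold higher in the deletion, by 3.39 ± 0.32 (adjusted p = 0.00263). STE3, the receptor for a-factor, was higher by 2.23 ± 0.16 (adjusted p = 0.000925), and the peroxiredoxin AHP1 by 1.86 ± 0.16 (adjusted p = 0.002). COS12 (YGL263W; chromosome VII, 2790 to 3932), a gene near a chromosome end, was lower by -3.20 ± 0.18 (adjusted p = 0.000585), as were the IMP dehydrogenase gene IMD2 (-2.24 ± 0.14) and RPM2, a protein of mitochondrial RNase P (-1.27 ± 0.12). Of 43 mitochondrial ribosomal protein genes 17 were higher and none lower, and of 50 TCA cycle and respiratory chain genes 25 were lower and 4 higher.

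Also higher were the phosphoglycerate mutase homolog GPM2 (1.98 ± 0.26), YRO2 (1.96 ± 0.21), the Ran homolog GSP2 (1.94 ± 0.20), the glycerol phosphatase GPP2 (1.93 ± 0.19), the glutathione transferase GTT1 (1.76 ± 0.18) and UGX2 (1.75 ± 0.29). Also lower were the zinc transporter ZRT1 (-1.76 ± 0.26), ARO10 (-1.41 ± 0.21) and ARO9 (-1.40 ± 0.17) of aromatic amino acid breakdown, and the transcription factor ADR1 (-1.32 ± 0.26). Adjusted over the list alone, 30 mitochondrial ribosomal protein genes were higher, such as MRPS16 (0.63 ± 0.08). The median was 0.35, and the list passed camera (adjusted p = 6.86e-18) and fry (0.0122), with adjusted p = 0.263 with an estimated correlation. Adjusted over the list alone, 29 respiratory genes were lower and 5 higher. The cytochrome oxidase genes COX5A (-1.11 ± 0.10) and COX4 (-0.93 ± 0.10) were lower, and IDH2 (1.02 ± 0.22) and LSC2 (0.73 ± 0.13) of the TCA cycle were higher. The list passed camera (adjusted p = 8.86e-09), with adjusted p = 0.753 with an estimated correlation. Of 37 autophagy genes 11 were higher and 19 adjusted over the list alone, such as ATG40 (1.37 ± 0.12); of 19 phosphate regulon genes 5 were higher and 8 adjusted over the list alone, such as the acid phosphatase gene PHO11 (1.44 ± 0.17). By camera these had adjusted p = 9.48e-08 and 3.6e-06, and each had adjusted p = 0.447 with an estimated correlation. UGX2, ZRT1, ARO9, ARO10 and ADR1 missed the threshold without deletion untreated replicate 1, with adjusted p = 0.0741, 0.0741, 0.0518, 0.0787 and 0.11; ARO10 did so without its replicate 2 (0.0537) and ADR1 without each deletion library (0.0542 to 0.11). IDH2 missed it without each library but wild type untreated replicate 1 (0.0533 to 0.202), LSC2 without deletion untreated replicate 1 and 2 (0.11 and 0.0745), and MRPS16 without deletion untreated replicate 1 (0.0675). With only the 4 untreated libraries the genes named here except YRO2 and COX5A missed it (0.0539 to 0.125).

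No gene of the ribosomal protein list (137 genes, median -0.20), of ribosome biogenesis (149, -0.16), of translation (50, -0.18) or of the polymerase I and III machinery (36, -0.12) was called by edgeR in untreated cells. At an unadjusted p under 0.05 there were 14, 22, 6 and 6 such genes, and DESeq2 called 1, 2, 1 and 0. Camera placed the first 3 lists lower, with adjusted p = 0.000162, 2.22e-05 and 8.52e-05, but adjusted p = 0.798, 0.794 and 0.753 with an estimated correlation. The ribosome biogenesis median was -0.01 (adjusted p = 0.912) without wild type untreated replicate 2 and -0.07 (adjusted p = 0.0821) without deletion untreated replicate 1. Of genes reported as repressed by Rph1, 0 of 6 were called by edgeR, 3 adjusted over the list alone, 3 at an unadjusted p under 0.05 and 2 by DESeq2; ATG7 had 0.50 ± 0.13 (adjusted p = 0.0613) and ATG8 0.02 ± 0.28. General stress had 6 higher and 1 lower of 49, and camera gave adjusted p = 0.00606, with adjusted p = 0.798 with an estimated correlation. Its median of 0.22 turned to -0.17 without wild type untreated replicate 2 and to -0.15 without deletion untreated replicate 1. The iron regulon had 4 of 23 higher, such as the mRNA-decay factor TIS11 (0.93 ± 0.12). Camera called 14 of 24 lists in the untreated deletion, and 0 with an estimated correlation (smallest adjusted p = 0.263). The iron regulon, proteasome, retrograde response, amino acid biosynthesis and cyclins with G1/S genes were among the 14. Of the alpha-specific genes 1 of 3 was higher, and of the a-specific genes AGA2 was higher (1.04 ± 0.09) and MFA2 lower (-0.76 ± 0.14). Without deletion untreated replicate 1, TIS11 (adjusted p = 0.0518) and MFA2 (0.155) missed the threshold, as did MFA2 without wild type untreated replicate 2 (0.0779) and TIS11 and MFA2 with only the 4 untreated libraries (0.0672 and 0.106).

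In all, 301 genes were higher and 156 lower in the untreated deletion, 54 and 21 of them over 2-fold. With a term for the replicate number more genes were called, and 54.5% of them were higher, against 65.9% without it. Against the 457 calls, 54 were made without deletion untreated replicate 1, 149 without its replicate 2, 238 without wild type untreated replicate 2, 273 and 272 without deletion rapamycin replicate 1 and 2, 498 without wild type untreated replicate 1, 14 with only the 4 untreated libraries, and 703 by DESeq2. The over 2-fold count of 75 was 31 without deletion untreated replicate 1 and 133 without wild type untreated replicate 1.

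Under rapamycin the deletion asks what Rph1 does when TORC1 is inhibited, and here transcripts for ribosome production were higher in the deletion than in wild type. The helicase ROK1 was higher by 1.27 ± 0.11 (adjusted p = 0.000613), the ribosome assembly factor UTP23 by 1.17 ± 0.10 (adjusted p = 0.000613), RPL3 (YOR063W; chromosome XV, 444686 to 445849) by 1.05 ± 0.16 (adjusted p = 0.00353) and the RNA polymerase I subunit gene RPA135 by 0.98 ± 0.12 (adjusted p = 0.00181). Respiratory genes were lower, COX6 (YHR051W) by -1.49 ± 0.10 and ATP3 by -1.37 ± 0.10 (adjusted p = 0.000584 each). The hexose transporter gene HXT4 was 5.26-fold higher, by 2.40 ± 0.34 (adjusted p = 0.00252), and the aldehyde dehydrogenase gene ALD2 5.44-fold lower, by -2.44 ± 0.18 (adjusted p = 0.000584).

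Of 149 ribosome biogenesis genes 125 were higher and none lower, 134 adjusted over the list alone (median 0.73), and of 137 ribosomal protein genes 85 were higher and none lower, 100 adjusted over the list alone (median 0.58). Camera gave adjusted p = 2.1e-35 and 4.42e-20, and fry 0.0134 and 0.0516; with an estimated correlation the values were adjusted p = 0.564 and adjusted p = 0.676. The ribosomal protein median was 0.42 without wild type rapamycin replicate 2 and 0.83 without its replicate 1. Polymerase I and III genes had 11 of 36 higher, and translation genes 11 of 50 higher, such as RPG1 (1.01 ± 0.12), and 1 lower, TYS1. By camera these had adjusted p = 0.00613 and 0.000152, and each had adjusted p = 0.676 with an estimated correlation. TYS1 lost its call without wild type rapamycin replicate 2 (adjusted p = 0.0516) and without deletion rapamycin replicate 1 and 2 (0.0689 and 0.0864). Of 43 mitochondrial ribosomal protein genes 30 were higher, 33 adjusted over the list alone, such as MRPL1 (0.81 ± 0.09); camera gave adjusted p = 1.39e-13, and adjusted p = 0.458 with an estimated correlation.

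**Figure D3:**
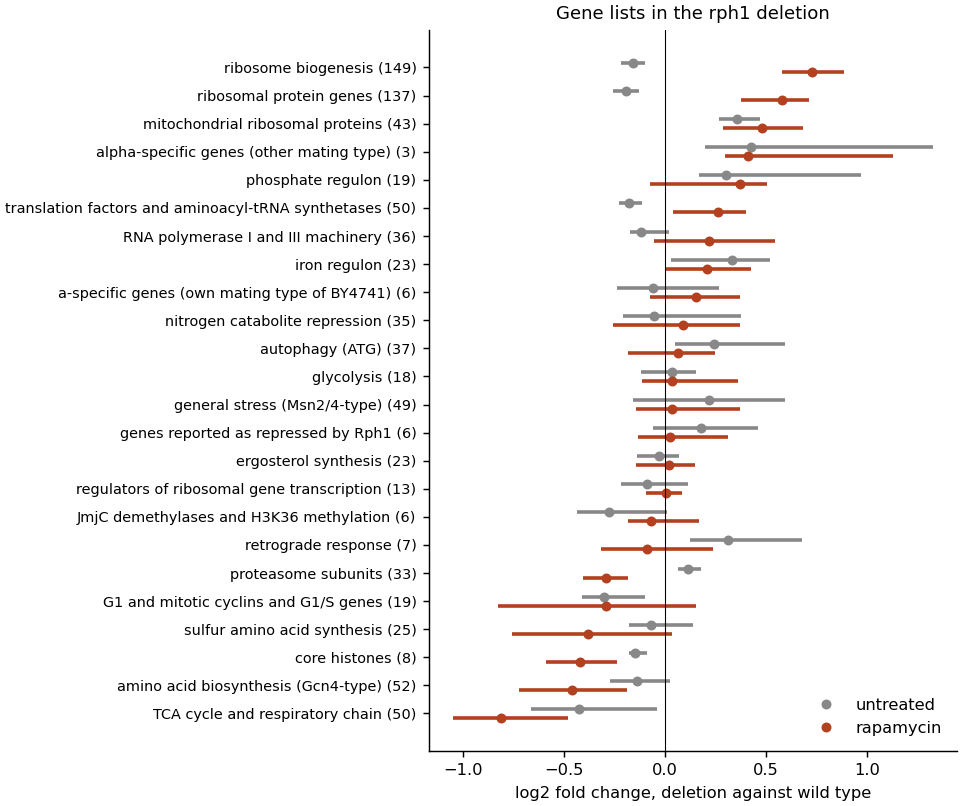
Log2 fold change of the deletion against wild type (x axis) for 24 gene lists with the number of genes tested; points are medians of members and bars span their quartiles, in untreated cells and with rapamycin. The ribosome biogenesis median was -0.16 untreated and 0.73 with rapamycin, and the respiratory median was -0.43 and -0.81.

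Of 50 TCA cycle and respiratory chain genes 38 were lower and 1, IDH1, higher, and 39 and 1 adjusted over the list alone, with a median of -0.81. Of 52 amino acid biosynthesis genes 28 were lower and none higher, 31 adjusted over the list alone, such as LYS1 (-1.15 ± 0.11) and HIS5 (-0.99 ± 0.10). Camera gave adjusted p = 9.07e-18 and 3.41e-10 for these lists and fry 0.013 for each; both had adjusted p = 0.564 with an estimated correlation. Sulfur amino acid genes had 10 of 25 lower, such as MET14 (-1.36 ± 0.13) and MET3 (-1.16 ± 0.11), and 2 higher, CYS4 and SAM1 (camera adjusted p = 0.00437; adjusted p = 0.594 with an estimated correlation). Of 33 proteasome genes 13 were lower, 17 adjusted over the list alone, such as PRE6 (-0.96 ± 0.09; camera adjusted p = 2.34e-06; adjusted p = 0.679 with an estimated correlation). Of 8 histone genes 3 were lower (camera adjusted p = 0.0106; adjusted p = 0.705 with an estimated correlation), such as HHF2 (-0.97 ± 0.18). The histone call was lost without wild type rapamycin replicate 1 (adjusted p = 0.103) and deletion rapamycin replicate 1 (0.0631), and HHF2 was lost without the latter (0.0607). IDH1 lost its call without each of the 4 rapamycin libraries (0.0964 to 0.153), and SAM1 without each library but the wild type untreated ones (0.0699 to 0.19).

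Nitrogen catabolite repression genes went both ways, with 9 of 35 higher, such as ATO3 (1.16 ± 0.10), and 7 lower, such as UGA4 (-1.31 ± 0.11). Autophagy had 2 of 37 higher and 3 lower, such as ATG1 (-0.75 ± 0.12). Of the genes reported as repressed by Rph1, 0 of 6 were called by edgeR, 0 adjusted over the list alone, 2 at an unadjusted p under 0.05 and 2 by DESeq2. Of 18 glycolysis genes 0 were called by edgeR, 2 had an unadjusted p under 0.05 and DESeq2 called 3. Cyclin and G1/S genes had 8 of 19 lower, CLN1 by -1.95 ± 0.19 and CLN2 by -0.87 ± 0.10, and 2 higher, the cyclin-dependent kinase inhibitor SIC1 (0.95 ± 0.10) and PCL9. STE3 was again higher (1.85 ± 0.14, adjusted p = 0.000605).

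Other large differences with rapamycin were higher SNR37 (2.03 ± 0.25), HXT6 (1.76 ± 0.40), YGP1 (1.76 ± 0.30), the U2 RNA LSR1 (1.72 ± 0.23), SNR30 (1.72 ± 0.29), the helicase DBP2 (1.69 ± 0.24) and the amino acid permease TAT1 (1.56 ± 0.27). COS12 (-2.79 ± 0.17), the lactate transporter JEN1 (-2.22 ± 0.25), SNZ1 (-2.17 ± 0.16), the cyclin PCL1 (-2.06 ± 0.38) and the transcription factor CIN5 (-2.03 ± 0.26) were lower. HXT6 missed the threshold without wild type rapamycin replicate 2, deletion rapamycin replicate 1 and its replicate 2 (adjusted p = 0.0966, 0.0847 and 0.0522), and PCL1 without deletion rapamycin replicate 1 (0.0602). In all, 891 genes were higher and 834 lower, 103 and 131 of them over 2-fold. Against the 1725 calls, 1100 and 939 were made without wild type rapamycin replicate 1 and 2, 647 and 895 without deletion rapamycin replicate 1 and 2, and 1994 without wild type untreated replicate 1. Of the 301 genes higher in the untreated deletion, 99 were also higher with rapamycin, where 43.5 would be shared if calls were independent, and 26 were lower. Of the 156 lower, 91 were also lower, where 21.1 would be shared, and 8 were higher.

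The interaction tests whether the rapamycin change differed between genotypes. The hexose transporter gene HXT2 fell with rapamycin in wild type (-0.70 ± 0.18, adjusted p = 0.00841) and rose in the deletion (1.49 ± 0.18, adjusted p = 0.00031), a difference of 2.19 ± 0.25 (adjusted p = 0.00631). Ribosome biogenesis transcripts fell less in the deletion: ROK1 differed by 1.42 ± 0.15 and UTP23 by 1.29 ± 0.13 (adjusted p = 0.00622 each). Some genes that rose strongly with rapamycin in wild type rose less in the deletion: ALD2 differed by -2.91 ± 0.26 (adjusted p = 0.00554), UGA2 by -2.53 ± 0.25 (adjusted p = 0.00622) and SNZ1 by -2.50 ± 0.23 (adjusted p = 0.00554). DAL80 and MEP2, which also rose strongly, did not pass the test (0.78 ± 0.59 and 0.32 ± 0.29). GPP2 (-2.32 ± 0.26), YPL264C (-2.09 ± 0.21) and GSP2 (-2.01 ± 0.28) also had lower values, and HXT6 (2.65 ± 0.63), SNR37 (2.08 ± 0.33), SPS4 (1.89 ± 0.31), SNR44 (1.87 ± 0.21) and YMR141W-A (1.86 ± 0.32) higher ones. HXT6 missed the threshold without each deletion library and without wild type rapamycin replicate 2 (adjusted p = 0.0772 to 0.114), and SPS4 and YMR141W-A without deletion rapamycin replicate 1 (0.0547 and 0.0572).

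Of 149 ribosome biogenesis genes 111 had a higher rapamycin change in the deletion, 134 adjusted over the list alone (median 0.93), and of 137 ribosomal protein genes 51, and 116 adjusted over the list alone (median 0.77). The ribosomal protein median was 0.56 without wild type rapamycin replicate 2 and 0.96 without its replicate 1. Translation genes had 9 of 50 higher, 21 adjusted over the list alone, and the polymerase I and III machinery 7 of 36, 8 adjusted over the list alone. Lower changes were found for 14 of 52 amino acid genes, 8 of 25 sulfur amino acid genes, 8 of 33 proteasome genes and 7 of 37 autophagy genes, such as ATG33 (-1.37 ± 0.17). Camera called these 8 lists, with adjusted p from 6.73e-43 to 0.0139, and each had adjusted p = 0.617 with an estimated correlation. The respiratory list had 16 of 50 lower (camera adjusted p = 2.92e-09; adjusted p = 0.618 with an estimated correlation). Sulfur amino acid synthesis lost its call without wild type rapamycin replicate 2 (adjusted p = 0.0828). By fry, 0 of 24 lists passed; the smallest fry values were 0.0587, for ribosome biogenesis and for translation. In all 434 genes had a higher and 375 a lower change in the deletion, 134 and 120 of them over 2-fold. A term for the replicate number gave more calls, 53.3% of them higher, against 53.6% without it.

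Against the 809 interaction calls, 96 and 277 were made without deletion rapamycin replicate 1 and 2, 246 and 357 without deletion untreated replicate 1 and 2, 325 without wild type rapamycin replicate 2, 514 without wild type untreated replicate 2, and 1020 without wild type untreated replicate 1. The over 2-fold count of 254 was 84 without deletion rapamycin replicate 1, 161 without deletion untreated replicate 1 and 160 without wild type rapamycin replicate 2.

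The FLAG-Rph1 lists ask where the tagged protein was found on chromatin. In untreated cells 466 genes were listed, and 135 of 137 ribosomal protein genes were among them (98.5%, against 3.63% of 5780 other protein-coding genes). With rapamycin 705 genes were listed and 70 ribosomal protein genes were among them (51.1%, against 8.53%). The odds ratios were 1760 (95% interval 471 to 16400, Fisher's exact p = 5.4e-176) and 11.2 (7.79 to 16.1, Fisher's exact p = 1.75e-36). The authors' fold enrichment of listed ribosomal protein genes had a median of 59.6 untreated, led by RPL8A (YHL033C; chromosome VIII, 35255 to 36025) at 239, and of 19.9 with rapamycin; the other listed genes had 28.5 and 27.2. A stricter threshold was the median enrichment of the untreated list, 45.02, where the rapamycin list had a median of 25.3. Above 45.02, 107 ribosomal protein genes were listed untreated and 9 with rapamycin (odds ratio 2.47, 1.08 to 4.95, Fisher's exact p = 0.0161). This threshold removes more of the rapamycin list by construction, so these counts do not compare the conditions.

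All 70 ribosomal protein genes listed with rapamycin were also listed untreated, and 2 were in neither list. The lists shared 276 genes, where 46.7 would be shared if independent, and 190 were in the untreated list alone and 429 in the rapamycin list alone. The lists may differ in depth, so their sizes were not tested against each other. The 10 highest values untreated were rRNA genes and genes inside them on chromosome XII, such as RDN37-2 at 773 and RDN37-1 at 770, and 8 rRNA entries were listed untreated and 0 with rapamycin. The highest values with rapamycin were those of CIT2 at 1300 (YCR005C; chromosome III, 120946 to 122328), SPO24 at 791, CSS1 at 782, SED1 at 691, AHP1 and CCW12 at 619 each, and the glutamine synthetase gene GLN1 at 593. RPH1 itself was listed with rapamycin, at 17.0. Of 7 retrograde genes 0 were listed untreated and 7 with rapamycin, of 33 proteasome genes 1 and 25, of 52 amino acid genes 5 and 38, of 50 respiratory genes 2 and 23, and of 35 nitrogen catabolite repression genes 1 and 11. Ribosome biogenesis had 26 and 12 of 149, glycolysis 13 and 14 of 18, core histones 8 and 8 of 8, and mitochondrial ribosomal proteins 0 and 0 of 43. None of the 6 genes reported as repressed by Rph1 was in either list. Listing followed transcript abundance: of the other genes among the 100 most abundant transcripts of the wild type, 83.3% were listed untreated and 82.7% with rapamycin, against 0.85% and 3.77% of those ranked 801 to 5753.

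**Figure D4:**
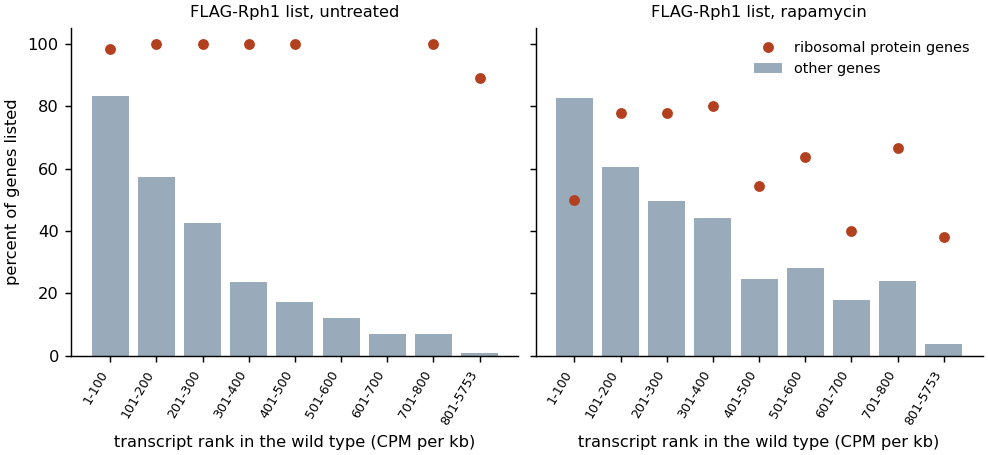
Percent of genes listed with FLAG-Rph1 (y axis) by transcript rank in wild type cells of the same condition (x axis, rank 1 the most abundant); bars are other genes and points ribosomal protein genes. Among other genes ranked 1 to 100, 83.3% were listed untreated and 82.7% with rapamycin.

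Genes listed in the rapamycin condition alone were mostly genes that the drug induced. Of 385 such genes tested, 254 rose and 49 fell with rapamycin in wild type (median 0.78), and 150 were lower and 13 higher in the deletion with rapamycin (median -0.33). Of 167 genes in the untreated list alone, 156 fell and 3 rose with rapamycin (median -2.56), and 90 were higher and 2 lower in the deletion with rapamycin (median 0.53). Of 258 genes in both lists, 184 fell and 37 rose with rapamycin, and 81 were higher and 29 lower in the deletion with rapamycin. Over all genes, the rapamycin change in the deletion was 0.755 of that in wild type, by slope. That alone would place induced genes lower and repressed genes higher in the deletion with rapamycin. The wild type libraries with rapamycin also enter both comparisons, with opposite sign. These differences can therefore not be tied to listing itself. As a set, the untreated list fell with rapamycin in wild type (340 of 425 lower, median -1.92) and was higher in the deletion with rapamycin (171 higher and 31 lower, median 0.40). Camera gave adjusted p = 1.57e-25 and 1.7e-09, but adjusted p = 0.0904 and adjusted p = 0.164 with an estimated correlation. Without ribosomal protein genes its medians were -1.27 (camera adjusted p = 2.31e-12; adjusted p = 0.0286 with an estimated correlation) and 0.24 (86 higher and 31 lower of 290; camera adjusted p = 0.00133; adjusted p = 0.19 with an estimated correlation). The rapamycin list was lower in the deletion with rapamycin (179 of 643 lower and 94 higher, median -0.16; camera adjusted p = 0.00156; adjusted p = 0.055 with an estimated correlation). Without ribosomal protein genes its median was -0.23 (camera adjusted p = 1.14e-06; adjusted p = 0.0104 with an estimated correlation). In untreated cells the deletion had 15 lower and 4 higher of the 425 genes of the untreated list (median -0.17; camera adjusted p = 7.2e-05; adjusted p = 0.321 with an estimated correlation).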

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

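The tests of library scaling, of a weaker response across all genes and of transcript level were chosen only after the result was seen. So were those of a peak assigned to several genes and of an extra or missing chromosome. The tests of gene length were prompted by the patterns below, and their bounds were set before their own values were seen. Each log2 value in this paragraph is a rapamycin change in the deletion minus that in wild type, and stood out because the interaction test passed. Genes with higher values were HXT6 (2.65), HXT2 (2.19), SNR37 (2.08), SPS4 (1.89), SNR44 (1.87) and YMR141W-A (1.86). Genes with lower values were GSP2 (-2.01), YPL264C (-2.09), GPP2 (-2.32), SNZ1 (-2.50), UGA2 (-2.53) and ALD2 (-2.91). HXT6 lost its call in 5 of the 8 fits without 1 library. List medians were higher for ribosome biogenesis (0.93), ribosomal proteins (0.77), translation factors with aminoacyl-tRNA synthetases (0.45) and RNA polymerase I and III (0.30). They were lower for autophagy (-0.22), sulfur amino acids (-0.28), TCA cycle with respiratory chain (-0.38), amino acid biosynthesis (-0.43) and the proteasome (-0.43). None of the list calls held with an estimated correlation (adjusted p = 0.617 or 0.618). That test called 0 of 24 lists in every comparison, also where nearly all members fell with rapamycin. It therefore does not set these lists apart.

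Ribosomal protein and ribosome biogenesis transcripts were higher in the deletion than in wild type under rapamycin. A scaling error would move all genes alike, but the smaller list median stood at least 0.415 (log2) above that of other genes whichever library was left out. Camera had already set these lists against other genes, so this value restates that result. Removing the trend on gene length left the smaller median at 0.622. The ribosome biogenesis change in the deletion was 0.441 of that in wild type (0.384 to 0.498 with 1 library left out), below 0.702 (0.671 to 0.764) for nitrogen catabolite repression and 0.811 (0.594 to 1.16) for general stress, which argues against 1 weaker response across all genes as its whole cause. Ribosome biogenesis did not stand apart from every list: amino acid biosynthesis had 0.369 (0.31 to 0.455) and core histones 0.467 (0.309 to 0.628). The fraction for ribosomal proteins, 0.754 (0.710 to 0.814), lay at the slope over all genes (0.755) and over genes outside the ribosomal lists (0.770, 0.706 to 0.836), so that part of the pattern is consistent with 1 weaker response across all genes. A different effective exposure to the drug, a difference between clones other than RPH1, and an action of Rph1 itself stay open. Of these, only repression confined to ribosomal protein genes listed under rapamycin was tested, for differences of at least 0.3.

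Genes in the FLAG-Rph1 lists were mostly genes with abundant transcripts. At equal transcript rank, ribosomal protein genes were listed more often than other genes. Within bands of 100 transcript ranks the common odds ratio was 286 (57.2 to 2910) untreated and 4.80 (3.16 to 7.32) with rapamycin. Ranks used counts per kb of gene length. Introns thus lower the rank of genes that hold them, and may raise these ratios where ribosomal protein genes do. Transcription rate was not examined, so the bands bear on transcript abundance only. These bands replaced a version that pooled genes below rank 800, and the next test a version that could not lower the percentile. Assignment of 1 peak to several neighbours is not the whole cause, since listed genes with no other listed entry within 2 kb had a median rank percentile of 96.4 (95.8 to 97.3) untreated and 91.5 (90.0 to 92.9) with rapamycin. Signal that strongly transcribed genes give in ChIP without the tagged protein may still contribute, since 83.3% of the other genes among the 100 most abundant transcripts were listed untreated; no untagged control was used here.

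Respiratory chain transcripts were lower and mitochondrial ribosomal protein transcripts higher in the deletion. An extra or missing chromosome would shift a chromosome's median by far more than the largest one seen, 0.098 (log2), and the lists are spread over 14 and 12 chromosomes. Removing the trend on gene length left the smaller shift at 0.509 with rapamycin and 0.343 untreated. The state of mitochondrial DNA stays open, because mitochondrial entries held 0 reads in all 8 libraries, as do a difference between clones and a biological role of Rph1.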

How the results depend on the processing

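The alternatives with ribosomal protein genes that have no paralog in the list and with each distinct enrichment value counted once were chosen only after the result was seen. At a depth of 18037199 to 24769193 counts, simulated data for the deletion with rapamycin recovered 95% of changes of 2-fold but 57% of those of 1.5-fold. The changed genes there lay above a minimum mean abundance, and deviations shared by many genes were not simulated. The 2 libraries per group limit all comparisons. With 1 library left out, the lone sample of its group is assumed to vary like the others. RLE scaling, TMM scaling without the ribosomal lists and both other low-count filters kept all 10 gene counts within 1.5 times. So did leaving out rRNA, tRNA and mitochondrial entries. These held 13 to 119, 729 to 2154 and 0 reads per library, too few to move the counts much. The largest shift of the median of all genes was -0.057, for rapamycin in wild type with TMM without the ribosomal lists. Planned windows of 500 and 1000 bp before the gene start and over the gene body, an overlap of 50% and covered lengths were not run, since the lists give no peak positions.

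The count for the untreated deletion (457) was 14 with only the 4 libraries of the comparison, which leaves fewer libraries to estimate the spread, and 703 by DESeq2; over 2-fold (75) it was 13 with only the 4 libraries. With the replicate block it was 1102, and the interaction count (809) was 1648; the cause was not tested. Differences between replicates correlated by 0.19 to 0.56 in the 6 pairs of groups, but groups share only a number, and with 2 replicate numbers all signs agree by chance at 0.125. Over the 8 fits without 1 library, counts ranged from 3605 to 4153 for rapamycin in wild type, 2570 to 3690 in the deletion, 54 to 498 for the untreated deletion (31 to 133 over 2-fold), 647 to 1994 for the deletion with rapamycin (157 to 254) and 96 to 1020 for the interaction (84 to 373). The lowest counts came without deletion untreated replicate 1 for the untreated deletion and without deletion rapamycin replicate 1 for the deletion with rapamycin and the interaction; the cause was not tested.

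The ribosomal protein medians lost their call with an estimated correlation: -3.039 and -2.293 with rapamycin in wild type and deletion, -0.196 and 0.578 for the deletion untreated and with rapamycin, and 0.765 for the interaction. Over fits without 1 library they ranged from -3.203 to -2.796, -2.349 to -2.198, -0.234 to -0.148, 0.418 to 0.827 and 0.557 to 0.963. With the 19 genes that have no paralog in the list they were -3.341, -2.380, -0.223, 0.705 and 0.901. In the untreated deletion the general stress median reversed to -0.166 without wild type untreated replicate 2 and to -0.15 without deletion untreated replicate 1 (highest 0.749). For rph1 deletion untreated, the median of list proteasome subunits reversed to -0.004 without wild type untreated replicate 2 and was highest, 0.227, without wild type untreated replicate 1. Of 120 list results, an estimated correlation ended 60 calls, which left 0 in every comparison, and DESeq2 ended 4 and added 4. Among 504 results of named genes, the replicate block added 18 calls and DESeq2 added 10, and neither ended any. Of 365 calls of named genes, 258 were kept in all alternatives and 107 were lost in at least 1, most with 1 library left out.

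Median and mean, or median and camera, differed in sign for lists near 0 that camera did not call: ergosterol genes in all but wild type with rapamycin, nitrogen catabolite repression in the untreated deletion and the interaction, sulfur amino acids and a-specific genes in 2 comparisons each, and regulators of ribosomal gene transcription, the phosphate regulon and cyclins in 1 each.

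Above an enrichment of 45.02 the lists held 231 genes untreated and 215 with rapamycin, and 67 in both, since the threshold itself removes genes. With an estimated correlation the untreated list lost its call with rapamycin in wild type (-1.919), in the untreated deletion (-0.167), in the deletion with rapamycin (0.402) and in the interaction (0.59), and the rapamycin list in the deletion untreated (-0.116) and with rapamycin (-0.16). Without ribosomal protein genes the rapamycin list gained calls with rapamycin in wild type (0.403) and in the interaction (-0.193) and lost that in the untreated deletion (-0.095); the cause was not tested.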

Other observations

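The groups of short RNAs, the 5S rRNA gene and the hexose transporters were chosen after their values were seen, as was the test of local repression. The test of chromosome ends was prompted by COS12, and its bounds were set before its own values were seen. Short RNAs, most of them snoRNAs that guide rRNA modification, fell with rapamycin: of 78 entries 57 fell and 8 rose in wild type (median -1.62), and 49 fell and 2 rose in the deletion (median -1.12). In the deletion against wild type 15 were higher and 7 lower with rapamycin, and 0 were higher and 6 lower untreated. Protein-coding genes held 99.69% to 99.75% of each library's counts, and rRNA entries 13 to 119 reads. Mature short RNAs may thus be poorly covered, and the changes may not be those of the mature RNAs. SNR30, needed for 18S rRNA processing, changed by -3.86 ± 0.29 in wild type (adjusted p = 1.16e-05) and by -2.02 ± 0.26 in the deletion (adjusted p = 0.000382), and the interaction was 1.84 ± 0.38 (adjusted p = 0.0212). LSR1, the U2 spliceosomal RNA, fell in wild type (-1.49 ± 0.23, adjusted p = 0.000607) and had 0.07 ± 0.21 in the deletion (adjusted p = 0.804). The 5S rRNA gene entry RDN5-1 held 35 and 32 reads in untreated wild type, 105 and 87 in untreated deletion, 12 and 17 in wild type with rapamycin, and 100 and 118 in deletion with rapamycin. It was higher in the deletion untreated (1.44 ± 0.24, adjusted p = 0.0149) and with rapamycin (2.78 ± 0.28, adjusted p = 0.000966), with an interaction of 1.35 ± 0.38 (adjusted p = 0.0561). These are few reads of a repeated gene, so another probe of 5S rRNA, such as a Northern blot, would be needed.

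STE3, an alpha-specific gene, held 39 and 58 reads in untreated wild type, 241 and 230 in untreated deletion, 95 and 77 in wild type with rapamycin, and 312 and 360 in deletion with rapamycin. The alpha-factor gene MF(ALPHA)1 held 3 to 12 reads per library and MF(ALPHA)2 92 to 163. MF(ALPHA)2 did not pass the test untreated (0.42 ± 0.18, adjusted p = 0.2) or with rapamycin (0.18 ± 0.18, adjusted p = 0.492), and the alpha-specific agglutinin gene SAG1 did not pass the test untreated (-0.03 ± 0.12, adjusted p = 0.915). With rapamycin SAG1 was higher in the deletion (0.41 ± 0.12, adjusted p = 0.0399), a call lost without wild type rapamycin replicate 1 and deletion rapamycin replicate 1 and 2 (0.146, 0.11 and 0.109). The list of STE3, SAG1 and MF(ALPHA)2, in which STE3 alone was called untreated, passed fry in both conditions (adjusted p = 0.0377 untreated and 0.00657 with rapamycin); fry was not run without STE3. By camera it had adjusted p = 0.0302 untreated, lost without wild type untreated replicate 1 (0.113) and deletion untreated replicate 2 (0.0637). With rapamycin camera gave 0.0534, and 0.0221 and 0.041 without wild type and deletion rapamycin replicate 2; with an estimated correlation the values were 0.447 and 0.564. Of the hexose transporter genes, which were not tested as a group, HXT2 was higher in the deletion with rapamycin by 1.17 ± 0.18 (adjusted p = 0.0033), and HXT4 with rapamycin was at 599 ± 247 CPM (SD, n = 2) in the deletion and 114 ± 14.8 in wild type.

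Rph1 may repress the ribosomal protein genes at which it was listed under rapamycin. If it acted at these genes alone, the 70 listed genes would be higher in the deletion with rapamycin than the 67 unlisted ones by at least 0.3 (log2). Their medians were 0.612 and 0.568, a difference of 0.045 (95% interval -0.05 to 0.165; permutation p = 0.377, two-sided), and the upper bound lies below that size. The interval and the p-value treat genes as independent and cover the spread over genes, not over libraries. Copies of some pairs were split between the groups, such as RPL12A (listed) and RPL12B (unlisted). Reads counted for both copies would shrink the difference. Within these limits, no effect of that size confined to the genes listed under rapamycin was seen. Repression at listed and unlisted genes alike would give no difference, so it was not tested. Of the 137 genes 135 were listed untreated, which leaves no comparison there.

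COS12 lies near a chromosome end and was lower in the deletion in both conditions, and silencing at chromosome ends may have changed as a whole. The higher median of the other 216 genes within 20 kb of an end was 0.028, in untreated cells, with 17 higher and 6 lower. With rapamycin the median was -0.217, with 12 higher and 53 lower, against 0.005 for the rest. The untreated value does not show a common decrease, and the value with rapamycin falls between the bounds set for the test, so the question stays open.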
